A study of Mus musculus with 8 samples.

How the data were processed

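Single-cell RNA libraries of mouse calvarial bone marrow were analysed from the UMI count matrices as the authors deposited them, with whole-number counts of UMIs per gene and cell barcode that had not been normalized. Per the labels' protocols the bone was ground and strained, the remaining pieces were digested with collagenase IV, DNase and Dispase at 37 °C for 30 min, both fractions were recombined and sorted, and libraries were made with a 10x kit of version 3.1, in 1 protocol given for all libraries. Per the submitters' processing notes the counts came from Cell Ranger 7.0.1 and the mm10 genome. Settings of that step are not given in the sources used here. Groups came from the labels, as week 1 hotspot (2 libraries), week 1 coldspot (2), week 1 control without Tet2 mutant cells (1 with counts), week 22 hotspot (1) and week 22 coldspot (1). Control replicate 1 was not used here, since no counts were at hand for it. Per the labels a library held cells of 1 mouse (replicate 1 at week 1), 2 mice (replicate 2) or 3 mice (week 22), so the p-values measure the spread between pools of unlike size.

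The 7 libraries held 46508 barcodes and 33697 features, of which 31961 (94.85%) matched a gene of GENCODE vM21, from which the coordinates were taken. Barcodes with at least 500 UMIs, 250 genes and at most 10% mitochondrial UMIs were kept (42136), and Scrublet, as run in scanpy with an expected rate of 6%, removed between 0.866% and 3.32% of them per library as doublets, leaving 41328 cells. The filter on mitochondrial UMIs took 920 barcodes from the control and between 29 and 183 from each of the others. Counts were scaled to 10000 per cell and logged, and 2000 variable genes were centred and scaled within each library. Cells were then clustered by the Leiden method on 30 principal components and 15 neighbours at a resolution of 0.6, which was set after looking at the clusters. The 41 clusters were named from 24 marker lists by their score, with at least 3 markers detected in 10% of cells and no more markers of another type than of their own among the 10 leading genes. The monocyte cluster led by Apoe and Adgre4 (677 cells) had 0 monocyte markers among these 10 and was named by its score, with 12 markers detected. Class names are to be read as cells like that type. A rule that keeps precursors out of a class was set after looking. It left 1 cluster of 321 cells unnamed, beside 2 others of 1112 and 61 cells that stayed unnamed, and unnamed cells made up between 2.27% and 6.69% of each library.

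UMIs were summed per library and class, and sums of at least 10 cells were tested. Coldspot replicate 1 held 9 macrophages, so a minimum of 5 cells was used for them, chosen after the data were seen. The tests were edgeR's quasi-likelihood tests (glmQLFit and glmQLFTest) with TMM factors, filterByExpr, robust estimation and Benjamini-Hochberg adjustment at 0.05 within each class and comparison. Hotspot against coldspot at week 1 had its own fit (9886 genes in mature neutrophils), and the comparisons with the control shared another of all week 1 groups (11543 genes). Counts over several classes are sums of adjusted calls. The comparisons, their tests, the gene lists, the panel, the markers and most alternatives were fixed before the data were seen. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists of 1 class and comparison. None of the camera calls held with an estimated correlation. That test has few residual degrees of freedom, so a miss decides nothing and the calls stay unchecked. Fry called 1 list, complement in the monocyte interaction, which it did not call with the block. The standard error (SE) of log2 fold changes was approximated from the fold change and F statistic and need not match the p. Shares were compared with two-sided exact permutation tests over libraries. Tests against the control, 1 library, assume that it varies like the hotspot and coldspot groups, as the interaction does for week 22. The week 22 sites were not tested against each other, with 1 library each, and both values are given with exact 95% Poisson or Clopper-Pearson intervals, which cover counting error only, and list medians are placed among 10000 random lists matched on mean expression with a CPM pseudocount of 1. A count of 0 was read against a floor of 3 counts.

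The 25 lists were NFkB and TNF inflammatory genes, interferon-stimulated genes, interferon gamma response, MHC class II, classically activated macrophage, alternatively activated macrophage, complement and efferocytosis, iron and heme recycling, alarmins and S100, neutrophil primary granule, neutrophil secondary and tertiary granule, neutrophil chemotaxis and retention, proliferation, glycolysis and hypoxia, oxidative phosphorylation, ribosomal proteins, dissociation and immediate early genes, lysosome, cholesterol synthesis, unfolded protein response, TGF-beta and fibrosis, red cell free RNA, B lineage free RNA, T and NK lineage, and hematopoietic niche factors. Genes were named by a fixed rule. For mature neutrophils, monocytes and macrophages it took up to 12 genes with the highest and 12 with the lowest log2 fold change among those past the threshold with a mean of at least 20 CPM and the same sign in each within-batch pair, without gene models, receptor and antibody segments and hemoglobins, and up to 3 each way for other classes. At week 22 it took up to 10 each way among genes with at least 50 UMIs and a ratio of at least 2, and for each list up to 4 members with the smallest p. A panel of 26 genes was always reported where tested. The rule was extended to the blocked fits after the data were seen. A few genes that it or the panel names are not reported here, and the counts of named genes under the alternatives leave them out.

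At week 1 the labelled batch follows the replicate number, so a fit with that number as a block is a valid pairing. Such a week 1 fit leaves 1 residual degree of freedom, so its p-values rest mostly on the spread of other genes. The deviations of same-batch hotspot and coldspot libraries from their group means correlated over genes, which are not independent replicates, at 0.508 in mature neutrophils, 0.597 in monocytes and -0.0199 in macrophages. Replicates differed beyond sampling noise, with chi-square per degree of freedom between 11.1 and 90.0, so none was a library counted again.

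The scripts were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. For hotspot against coldspot at week 1 in mature neutrophils (9886 genes) edgeR recovered 18% of the 2-fold and 67% of the 4-fold changes with 12 unchanged genes called, and with the block 31% and 90% with 4 called. For hotspot against control (11543 genes) it recovered 1% and 46% with 10 called, and with the block 11% and 64% with 6. Over both weeks (10680 genes) it recovered 34% and 85% with 5 called and with the block 60% and 92% with 15. Week 22 against week 1 (10680 genes) gave 30% and 82% with 10. The interaction (11599 genes) gave 0% and 9% with 4, and with the block 1% and 49% with 4. EGFP-positive against EGFP-negative B progenitors (13291 genes) gave 69% and 84% with 35. Of 200 unchanged lists 0.5% to 4% had a camera p under 0.05. Simulated lists do not check the preset correlation.

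Alternatives were RLE size factors, DESeq2, no filter on low counts, the replicate block, doublets kept, stricter cells (1000 UMIs, 500 genes and 5% mitochondrial UMIs), no centring within libraries and leaving out each library. Every comparison that uses the EGFP feature was chosen after it had been seen. A cell was called EGFP-positive from 1 UMI, and shares were also taken after thinning each cell to 1000 UMIs. Tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, DESeq2 1.42.0, limma 3.58.1 and version 1.17.8 of data.table.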

Results

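Single-cell RNA libraries were made from calvarial bone marrow, the marrow of the skull bones, of mice transplanted with GFP-labelled cells heterozygous for Tet2. Tet2 encodes a dioxygenase that oxidises methylated cytosine in DNA, and it is often mutated in clonal haematopoiesis, the outgrowth of blood cells from a mutant stem cell. Marrow came from hotspots, where the transplanted cells had expanded, from coldspots, where they had been suppressed, and from control sites without Tet2 mutant cells. At week 1 after transplantation there were 2 hotspot libraries, 2 coldspot libraries and 1 control library with counts. Replicate 1 of each site came from 1 mouse and replicate 2 from 2 pooled mice, and the replicate number was also the batch. Week 22 had 1 hotspot and 1 coldspot library, each pooled from 3 mice, in another batch. Control replicate 1 was not analysed. GFP-positive and GFP-negative cells had been sorted and recombined before capture, so the sort can set shares of cell types and of donor cells.

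Counts were of UMIs (unique molecular identifiers), each 1 captured RNA molecule. At week 1 the libraries held 87947325 UMIs in hotspot replicate 1, 84340254 in hotspot replicate 2, 23796276 in coldspot replicate 1, 108611075 in coldspot replicate 2 and 106685330 in control replicate 2. At week 22 the hotspot library held 174795655 UMIs and the coldspot library 130974927. After filtering, 6157, 5470, 1947, 6617, 6678, 8365 and 6094 cells were kept in the same order, with median UMIs per cell between 7019 in coldspot replicate 1 and 16455.5 in the week 22 coldspot. Mature neutrophils, monocytes and macrophages were compared in full and 10 other cell classes more briefly. Macrophages were few, with 44 and 45 cells in the week 1 hotspot libraries, 9 and 53 in the coldspot libraries, 46 in the control, 101 in the week 22 hotspot and 110 in the week 22 coldspot.

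Tet2 (ENSMUSG00000040943, mm10 chromosome 3, 133463679 to 133545139, a protein-coding gene) was read in each class at each site. In mature neutrophils at week 1 it stood at 89.0 ± 31.8 CPM (UMI counts scaled to a common total; SD, n = 2) in hotspots, 79.7 ± 37.7 (SD, n = 2) in coldspots and 71.8 CPM in the control. In monocytes the values were 144.5 ± 82.5, 147.3 ± 97.6 and 125.1 CPM. The log2 fold change of hotspot over coldspot was 0.20 ± 0.40 (SE) in mature neutrophils and 0.02 ± 0.59 in monocytes, both within the error. Tet3 stood at 29.4 ± 5.95 CPM in hotspot and 33.0 ± 1.86 CPM in coldspot mature neutrophils, and Tet1 at under 1 CPM in both. The libraries mixed donor and host cells and read 3' ends, so these levels do not check the genotype.

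The share of each cell class per library was compared first. At week 1 B progenitors made up 22.0% ± 2.58 of hotspot cells and 15.9% ± 4.35 of coldspot cells (SD, n = 2 each), a difference of 6.13 points, with 7.38 in batch 1 and 4.89 in batch 2. It was 3.06 points without coldspot replicate 1 and 9.21 without coldspot replicate 2. Erythroid cells stood at 18.7% ± 0.0572 against 14.9% ± 3.71, a difference of 3.84 points, with 6.42 in batch 1 and 1.26 in batch 2. That difference was 1.22 points without coldspot replicate 1, 6.46 without coldspot replicate 2 and 0.882 with stricter cells, where batch 2 stood at -1.18. Immature neutrophils stood at 13.1% ± 2.36 against 18.6% ± 1.14, a difference of -5.48 points (-4.62 in batch 1 and -6.35 in batch 2), and mature neutrophils at 17.9% ± 3.02 against 22.4% ± 4.13, a difference of -4.46 points (-5.24 and -3.68). Monocytes made up 6.01% ± 0.295 against 7.08% ± 1.10, with a difference of -2.06 points in batch 1 and -0.0862 in batch 2, and macrophages 0.769% ± 0.0764 against 0.632% ± 0.240. With stricter cells the differences were -1.59 points for immature neutrophils, -2.15 for mature neutrophils and -0.418 for monocytes, while unnamed cells, which then held clusters scoring best as immature neutrophils, made up 15.3% of hotspot and 21.7% of coldspot cells. The exact two-sided permutation p was 0.333 for B progenitors, erythroid cells, immature neutrophils and monocytes and 0.667 for mature neutrophils and macrophages, and 0.333 is the smallest p that 2 libraries against 2 allow. Without coldspot replicate 1 the macrophage difference of 0.137 points turned to -0.0323, and the mature neutrophil and monocyte differences were -1.54 and -0.295 points; without coldspot replicate 2 the 3 were 0.306, -7.38 and -1.85. Without hotspot replicate 2 the mature neutrophil difference was -2.33 points and the macrophage difference 0.0830. The control held another mix, with 37.6% mature neutrophils, 26.4% immature neutrophils and 11.5% monocytes, but 1.71% B progenitors and 0.689% erythroid cells. At week 22 the hotspot held 19.6% B progenitors against 12.6% in the coldspot, 15.2% erythroid cells against 20.4%, and 1.35% eosinophils (113 cells) against 0.525% (32 cells).

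Whether the hotspot was inflamed relative to the coldspot at week 1 was asked first in mature neutrophils. Inflammatory genes of the NFkB and TNF list stood higher in hotspot than in coldspot neutrophils, with all 25 measured members above 0 and a median log2 fold change of 1.00. Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139), the gene of the cytokine interleukin 1 beta, stood at 1225 ± 762 CPM in hotspots and 619.7 ± 53.1 in coldspots (SD, n = 2). Cxcl2 (ENSMUSG00000058427, chromosome 5, 90903871 to 90905938), a chemokine gene that attracts neutrophils, stood at 943.6 ± 584 and 455.4 ± 7.95 CPM. The height lay mainly in hotspot replicate 1, with 1764 CPM of Il1b against 685.7 in hotspot replicate 2. Within batches the list's median log2 ratio was 1.28 in batch 1 and 0.31 in batch 2. Over 4315 genes with a mean of at least 20 CPM, which are not independent replicates, the hotspot to coldspot ratios of the batches ran against each other (Pearson r = -0.263, Spearman rho = -0.32), as they did over 6205 genes of monocytes (-0.322 and -0.288). A cluster led by Il1b and Csf3r held 27.8% of hotspot and 27.8% of coldspot neutrophils in batch 1 and 50.1% and 38.8% in batch 2. A cluster led by Cxcl2 and Il1b held 25.95% and 5.691%, and 2.09% and 1.87%. By camera with its preset correlation the list was higher in hotspots (adjusted p = 1.81e-21), and adjusted p = 0.502 with an estimated correlation. Single genes did not pass in the fit without a block, where edgeR called 0 of 9886 genes, with 73 at an unadjusted p under 0.05 and 0 by DESeq2, and 0 list members passed adjusted over the list alone.

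With the replicate block edgeR called 14 genes in mature neutrophils, 13 higher and 1 lower in hotspots. Among them was Ccl4 (ENSMUSG00000018930, chromosome 11, 83662584 to 83664683), a chemokine gene, at a log2 fold change of 1.73 ± 0.27 (SE; adjusted p = 1.1e-06). Tnfaip3, whose product restrains NFkB signalling, rose by 1.42 ± 0.30 (adjusted p = 0.0043), and Fosl1, a subunit gene of the AP-1 transcription factor, by 1.41 ± 0.29 (adjusted p = 0.0033). Dusp5, a phosphatase gene of the MAP kinase pathway, rose by 1.34 ± 0.31, Ccrl2, an atypical chemokine receptor gene, by 1.30 ± 0.29, and the early response gene Ier3 by 1.11 ± 0.27. Of the 25 NFkB and TNF members 4 rose with the block over all genes and 16 adjusted over the list alone. Without hotspot replicate 1, and without the block, Tnfaip3 stood at -0.35 and Fosl1 at -0.01.

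Genes of the neutrophil primary granule, the store of proteases made early in neutrophil development, formed a second group. All 5 measured members stood higher in hotspot neutrophils, at a median of 1.17, with 0 passing over all genes and 4 adjusted over the list alone (camera adjusted p = 5.22e-15, and adjusted p = 0.377 with an estimated correlation). Mpo (ENSMUSG00000009350, chromosome 11, 87793581 to 87804413), which encodes myeloperoxidase, stood at 17.9 ± 5.12 CPM in hotspots, 7.03 ± 1.20 in coldspots and 22.5 in the control, and rose with the block by 1.36 (adjusted p = 0.031). The protease genes Prtn3, Ctsg and Elane stood at 1.17 ± 0.34, 1.29 ± 0.43 and 1.04 ± 0.35 without the block. Within batches the list's median was 0.87 in batch 1 and 1.26 in batch 2. RNA of other cells moved with these groups, since all 10 B lineage transcripts (median 1.20) and all 8 red cell transcripts (median 0.63) also stood higher in hotspot neutrophils.

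Among immediate early and dissociation genes, 18 of 20 stood higher, at a median of 0.42, with 1 rising adjusted over the list alone (camera adjusted p = 3.33e-10, and adjusted p = 0.502 with an estimated correlation). That list was led by Fosb, another AP-1 gene, at 2.13 ± 0.48, and with the block Fosb rose by 1.91 (adjusted p = 6.5e-06). Camera also placed MHC class II (4 of 6 higher, median 0.84), classically activated macrophage genes (6 of 8, 0.62), and T and NK lineage (2 of 4, 0.67) higher in hotspots. It did the same for proliferation (16 of 19, 0.34), unfolded protein response (10 of 12, 0.21), ribosomal proteins (24 of 24, 0.16) and iron and heme recycling (8 of 9, 0.14). With red cell and B lineage RNA these made 12 of 25 lists. None of the 12 held with an estimated correlation, where the adjusted p lay between 0.377 and 0.594.

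The other 13 lists did not pass in mature neutrophils. Their medians were -0.12 for interferon-stimulated genes, -0.01 for the interferon gamma response, 0.15 for alternatively activated macrophage genes, 0.18 for complement and efferocytosis, 0.01 for alarmins and S100 genes, and 0.00 for the secondary and tertiary granule. Those of the rest were 0.05 for chemotaxis and retention, 0.08 for glycolysis and hypoxia, 0.02 for oxidative phosphorylation, 0.05 for lysosome, -0.13 for cholesterol synthesis, 0.09 for TGF-beta and fibrosis and 0.39 for hematopoietic niche factors, which passed with the block (camera adjusted p = 0.0133, and adjusted p = 0.791 with an estimated correlation). Single genes of the fixed panel did not pass, such as Tnf at 0.89 ± 0.37, the inflammasome gene Nlrp3 at 0.45 ± 0.27, the NFkB inhibitor gene Nfkbia at 1.11 ± 0.71, and Ccl3 at 1.01 ± 0.67. Nor did Ifit3 at 1.58 ± 0.69, Isg15 at 0.28 ± 0.40, S100a8 at -0.05 ± 0.28, Lcn2 at 0.04 ± 0.35, Cxcr2 at -0.03 ± 0.28 and Cxcr4 at 0.15 ± 0.36.

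**Figure D1:**
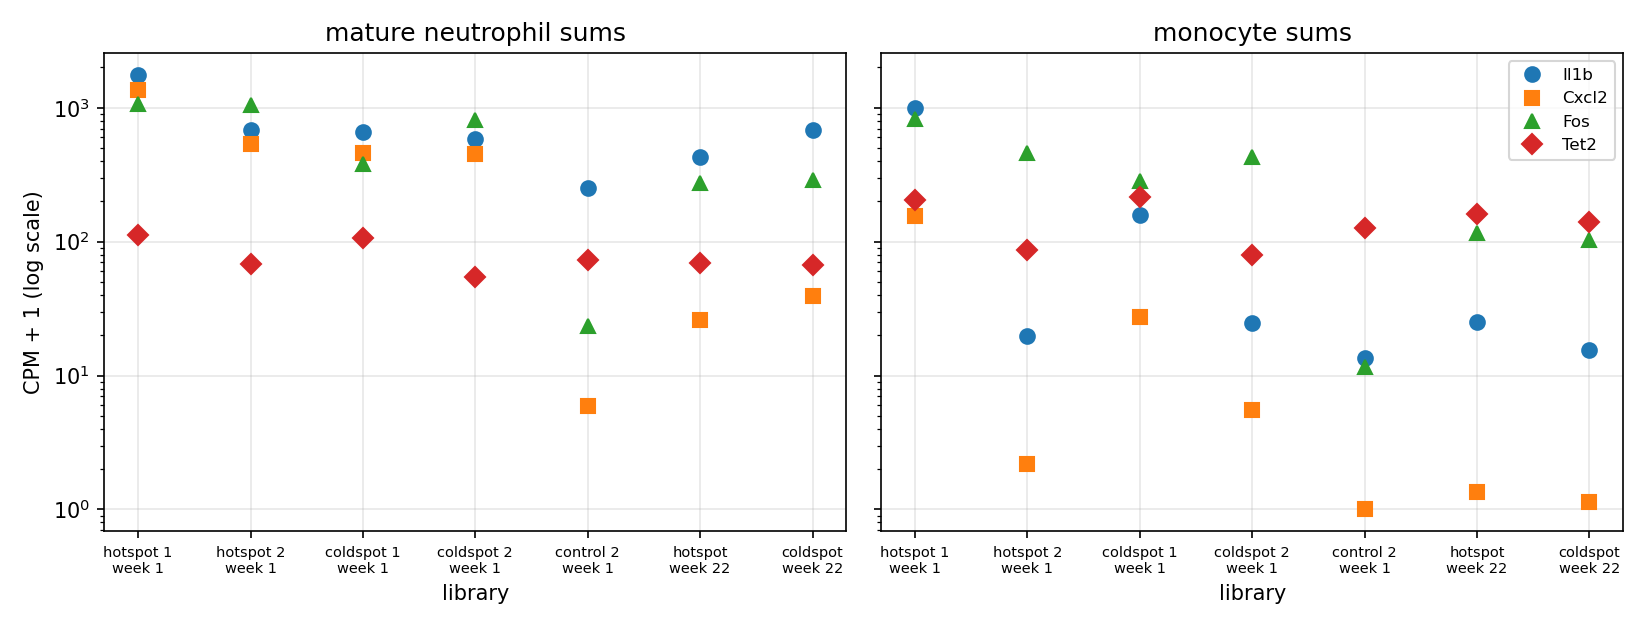
CPM plus 1 (log axis) of Il1b, Cxcl2, Fos and Tet2 in the summed mature neutrophils (left) and monocytes (right) of each library, 1 point per library and gene. Il1b and Cxcl2 of mature neutrophils were highest in week 1 hotspot replicate 1, at 1764 and 1356 CPM, and Fos was lowest in the control, at 22.4 CPM.

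In monocytes at week 1, antigen presentation and complement genes stood higher in hotspots than in coldspots. The mix of clusters differed too. The cluster led by Apoe and Adgre4 held 13.7% and 16.8% of hotspot against 29.4% and 25.2% of coldspot monocytes, and the cluster led by Fn1 and Ccr2 85.4% and 82.9% against 64.1% and 74.1%. Of 11 MHC class II genes 9 stood higher, at a median of 0.53, with 0.67 in batch 1 and 0.57 in batch 2. H2-Ab1, an MHC class II chain gene, stood at 610.0 ± 67.4 CPM in hotspots, 362.5 ± 8.64 in coldspots and 967.2 in the control, and the invariant chain gene Cd74 at 1767 ± 162, 1223 ± 73.0 and 2495 CPM. C1qb (ENSMUSG00000036905, chromosome 4, 136880129 to 136886187), a chain of the complement starter C1q, stood at 16.5 ± 2.27 CPM in hotspots and 1.85 ± 2.61 in coldspots. The C1q genes lead the macrophage cluster. Of its other leading genes Mrc1 stood at 22.5 ± 11.4 against 12.3 ± 6.39 CPM in these monocytes, Apoe at 1671 ± 72.4 against 1438 ± 127 and Hmox1 at 71.0 ± 18.7 against 77.5 ± 30.4. Of the 13 complement and efferocytosis genes 10 stood higher, at a median of 0.47, with 0.59 in batch 1 and 0.33 in batch 2. Camera called both lists (adjusted p = 1.33e-08 for MHC class II and 1.35e-10 for complement), with adjusted p = 0.551 and 0.456 with an estimated correlation, and 0 members passed over all genes.

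The monocyte NFkB and TNF list stood higher in 23 of 27 members, at a median of 0.49, with 0.66 in batch 1 and 0.13 in batch 2 (camera adjusted p = 5.14e-07, and adjusted p = 0.551 with an estimated correlation). Il1b was at 991.8 and 18.7 CPM in hotspot replicates 1 and 2 and 157.2 and 23.5 in coldspot replicates 1 and 2. S100a9 and S100a8 went with Il1b, at log2 ratios of 3.43 and 3.05 in batch 1 and -1.31 and -1.27 in batch 2. Free neutrophil RNA was not excluded. Without the block edgeR called 0 of 11200 genes, with 40 at an unadjusted p under 0.05 and 0 by DESeq2. With the block 8 genes passed, 5 higher and 3 lower, among them C1qb at 2.62 (adjusted p = 2.3e-05), C1qa at 2.63 (adjusted p = 0.009), and Ier3 at 2.01 ± 0.29 (adjusted p = 3.1e-08). The heat shock gene Hspa1b fell by 1.19 ± 0.28 (adjusted p = 0.04). Without the block, Ier3 stood at -0.51 when hotspot replicate 1 was left out and Hspa1b at 4.24 when coldspot replicate 1 was left out. Camera called 10 of 25 lists higher, with cholesterol synthesis (11 of 14, median 0.26), primary granule (4 of 6, 0.21), immediate early genes (13 of 21, 0.15), the unfolded protein response (12 of 13, 0.11), classically activated macrophage genes (7 of 9, 0.40), red cell RNA (8 of 8, 0.66) and B lineage RNA (10 of 10, 0.44) beside those above. None held with an estimated correlation (adjusted p = 0.456 at the lowest). With the block the call of immediate early genes was lost (camera adjusted p = 0.176) and alternatively activated macrophage genes passed (adjusted p = 0.0261, and adjusted p = 0.695 with an estimated correlation).

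In macrophages at week 1 cell cycle genes stood higher in hotspots than in coldspots in 8 of 8 members (camera adjusted p = 8.67e-05, and adjusted p = 0.856 with an estimated correlation). Top2a, a DNA topoisomerase gene, stood at 132.4 ± 120 against 6.77 ± 9.57 CPM (SD, n = 2), within the spread between replicates. The NFkB and TNF list did not pass, at a median of 1.22 with 12 of 14 members higher (adjusted p = 0.0587). Camera also placed red cell RNA higher (7 of 8, median 0.24) and the unfolded protein response lower (2 of 11 higher, median -0.24), at adjusted p = 0.00213 and 0.0261, with adjusted p = 0.856 for each with an estimated correlation. Red cell RNA differed between libraries too, with Hbb-bs at 167700 and 81740 CPM in the hotspots and 1705 and 185200 in the coldspots. EdgeR called 0 of 3780 genes, with 56 at an unadjusted p under 0.05 and 0 by DESeq2; with the block it called 1, the protease inhibitor gene Slpi at -5.15 ± 0.46 (adjusted p = 0.0021). Between 7 and 21 genes passed when 1 library was left out, 9 without hotspot replicate 1, 21 without hotspot replicate 2 and 7 without either coldspot replicate.

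**Figure D2:**
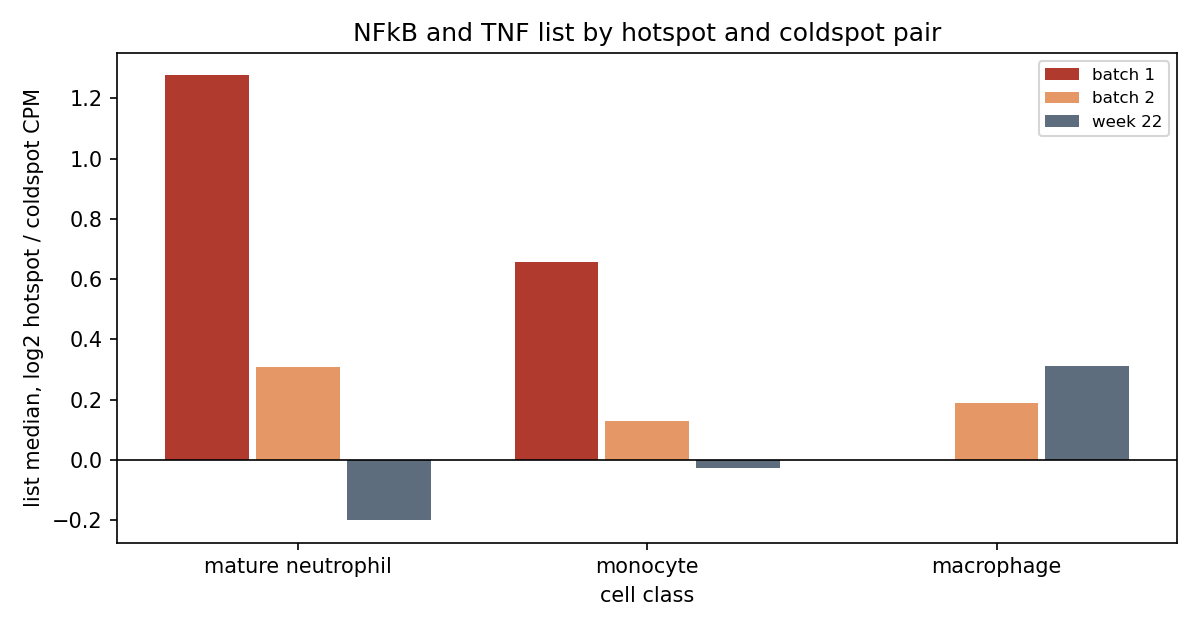
Median log2 ratio of hotspot over coldspot CPM for the NFkB and TNF list (vertical axis) in each cell class, 1 bar per hotspot and coldspot pair, with no bar for macrophages of batch 1, where coldspot replicate 1 held 9 cells. In mature neutrophils the median was 1.28 in batch 1, 0.31 in batch 2 and -0.20 at week 22.

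In the other 10 classes the fit without a block called 1 gene of hotspot against coldspot at week 1, with 1375 of 99155 tests at an unadjusted p under 0.05 and 7 genes by DESeq2. It was Retnlg, a neutrophil resistin-like gene, in plasmacytoid dendritic cells at 2.75 ± 0.31 (adjusted p = 0.02), and did not pass with doublets kept, with stricter cells, with no centring or without either coldspot replicate. With the block 85 genes passed. In granulocyte-monocyte progenitors Ltf, the lactoferrin gene, fell by 1.36 ± 0.09 (adjusted p = 5.1e-07), Lcn2 by 0.76 ± 0.07 and Camp by 0.52 ± 0.05. The spermidine synthase gene Srm rose by 0.64 ± 0.13 and the chaperone gene Calr by 0.48 ± 0.08. In B cells the mitotic genes Ube2c and Cenpf fell by 1.86 ± 0.27 and 1.86 ± 0.30 and Egr1, an early response transcription factor gene, rose by 1.14 ± 0.27. In NK cells Ccl4 rose by 3.34 ± 0.43 (adjusted p = 0.0064), together with the neutrophil genes S100a8 by 2.09 ± 0.24 and S100a9 by 1.79 ± 0.26. In stem and progenitor cells Fos rose by 2.30 ± 0.26 (adjusted p = 0.0094) and the heat shock gene Hspa1a fell by 2.74 ± 0.33 (adjusted p = 0.01). In plasmacytoid dendritic cells Il1b rose by 4.46 ± 0.43 and Ifitm1 by 1.57 ± 0.32, and Cd69, an early activation marker gene, fell by 1.43 ± 0.35. Without the block, Hspa1a of stem and progenitor cells stood at 3.51 when coldspot replicate 1 was left out and Ifitm1 at -0.62 when hotspot replicate 1 was left out. In the same fit S100a8 and S100a9 of NK cells stood at -1.47 and -1.78 with doublets kept, and Cd69 of plasmacytoid dendritic cells at 0.76 with no centring. The summed count was 132 without hotspot replicate 1, 211 without hotspot replicate 2, 150 without coldspot replicate 1 and 596 without coldspot replicate 2.

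The hotspot was then compared with the control, marrow without mutant cells, at week 1. The control was 1 library of batch 2, so its own spread was not measured. Each test against it, blocked or not, takes the spread from the site replicates and other genes and assumes that the control varies alike. In mature neutrophils 4 genes rose in hotspots and 0 fell. They were Cxcl2 at 7.93 ± 0.85, the early response gene Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273) at 5.88 ± 0.67, the circadian gene Per1 at 3.87 ± 0.45 (adjusted p = 0.038 each) and Plk2, a polo-like kinase gene that was named only after its values were seen. Cxcl2 stood at 943.6 ± 584 CPM in hotspots (SD, n = 2) and at 4.96 CPM (95 UMIs) in the control. All 26 NFkB and TNF genes stood higher, at a median of 2.09, with 1 rising over all genes and 14 adjusted over the list alone (camera adjusted p = 1.26e-20, and adjusted p = 0.576 with an estimated correlation). All 22 immediate early genes stood higher, at a median of 1.95, with 1 rising over all genes and 12 adjusted over the list alone (camera adjusted p = 2.58e-22, and adjusted p = 0.576 with an estimated correlation). Interferon-stimulated genes stood lower, with 8 of 25 above 0 and a median of -0.31 (camera adjusted p = 0.0105, and adjusted p = 0.617 with an estimated correlation). All 8 red cell transcripts stood higher too, with Hbb-bs at 11760 and 11310 CPM against 34.1 in the control. Of the control's mature neutrophils 99.5% lay in 1 cluster (led by Csf3r, Mmp9 and Cxcr2) that held 1.87% and 1.86% of those of the hotspots.

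With the replicate block 567 genes passed in mature neutrophils, 497 higher and 70 lower. Ptgs2, the gene of the prostaglandin enzyme COX-2, rose by 5.94 ± 0.45 (adjusted p = 2.3e-35), Egr1 by 5.94 ± 0.47 (adjusted p = 1.7e-32), Ccrl2 by 5.55 ± 0.58 and the cytokine gene Osm by 4.12 ± 0.43. The mitochondrial gene mt-Nd3 fell by 1.30 and the stress sensor kinase gene Ern1 by 1.21. The control also had 920 barcodes above the mitochondrial limit, against 29 to 183 elsewhere. Fpr3, a formyl peptide receptor gene, fell by 1.82 ± 0.36 but stood at 0.12 without hotspot replicate 2 in the fit without the block. Without the block, with 922 of 11543 genes at an unadjusted p under 0.05, DESeq2 called 202 genes. EdgeR called 43 without hotspot replicate 1, 386 without hotspot replicate 2, 20 without coldspot replicate 1, 49 without coldspot replicate 2 and 0 with stricter cells.

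In monocytes of the hotspot against the control, immediate early genes stood higher and interferon gamma response genes lower. Of 21 immediate early genes 20 stood higher, at a median of 1.55, with 4 rising adjusted over the list alone (camera adjusted p = 2.24e-15, and adjusted p = 0.566 with an estimated correlation). They were led by Fos at 6.04 ± 0.65 and Dusp1, a MAP kinase phosphatase gene, at 4.94 ± 0.76. Of 22 interferon gamma genes 3 stood higher, at a median of -0.76 (camera adjusted p = 5.97e-07, and adjusted p = 0.566 with an estimated correlation). MHC class II genes stood lower in 8 of 11, at a median of -0.53 (adjusted p = 0.0141, and adjusted p = 0.637 with an estimated correlation), a call that was lost with the block (adjusted p = 0.0823). Of 5 lists that camera called lower 2 passed with the block, interferon gamma response and alternatively activated macrophage genes. Oxidative phosphorylation genes stood higher in 23 of 24, at a median of 0.44 (adjusted p = 0.000116, and adjusted p = 0.637 with an estimated correlation). EdgeR called 0 of 12293 genes, with 533 at an unadjusted p under 0.05 and 27 by DESeq2, and 34 without hotspot replicate 1 and 91 without hotspot replicate 2. With the block 322 genes passed, 169 higher and 153 lower. Fos rose by 6.03 ± 0.41 (adjusted p = 1.3e-40), Dusp1 by 4.95 ± 0.43, the nuclear receptor gene Nr4a2 by 3.54 ± 0.41 and Osm by 3.35. Fcgr4, an antibody receptor gene, fell by 1.96 ± 0.31 (adjusted p = 1e-07), Tgfbr3 by 1.96 ± 0.36, Tcf7l2 by 1.95 ± 0.33 and Cd274, the gene of the checkpoint ligand PD-L1, by 1.70. The class lay in different clusters. A cluster led by S100a4 and Fn1, with H2-Ab1 among its leading genes, held 62.1% of control monocytes against 0.840% and 0.294% of those of the hotspots. A cluster led by Apoe and Adgre4, with Cx3cr1 among its leading genes, held 33.4% against 13.7% and 16.8%, and a cluster led by Fn1 and Ccr2 held 4.56% against 85.4% and 82.9%. With no centring within libraries, a cluster led by Fn1 and Ccr2 held 483 cells of the control and 177 and 277 of the hotspots. The split between the Fn1-led clusters was thus not kept.

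In macrophages of the hotspot against the control, edgeR called 68 genes, 60 higher and 8 lower, and several of the higher genes named by the fixed rule are red cell genes. The macrophages also differed in depth, with a median of 1519.5 and 2242 UMIs per cell in the hotspots, 1763 and 1690 in the coldspots and 8938 in the control. Slc4a1, the anion exchanger gene of red cells, had 30 and 180 UMIs in the hotspots and 0 in the control. Of the 8 red cell transcripts 7 rose, and Hbb-bs stood at 167700 and 81740 CPM against 2814. Cell cycle genes stood higher in 18 of 18, with 4 rising over all genes and 13 adjusted over the list alone (camera adjusted p = 1.6e-21, and adjusted p = 0.811 with an estimated correlation). B lineage transcripts stood higher in 10 of 10, at a median of 2.13, with 2 rising over all genes, and Kcnq5 and Cecr2, leading genes of B progenitor clusters, rose as well. Secondary granule genes stood lower in 14 of 14, with 6 falling adjusted over the list alone (camera adjusted p = 6.41e-12, and adjusted p = 0.865 with an estimated correlation). Fpr2, a formyl peptide receptor gene, fell by 2.98 ± 0.84 (adjusted p = 0.038). DESeq2 called 2 genes, and edgeR 165 without hotspot replicate 1, 41 without hotspot replicate 2, 110 without coldspot replicate 1 and 121 without coldspot replicate 2.

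The coldspot was compared with the control in the same way. In mature neutrophils 21 of 22 immediate early genes stood higher in coldspots, at a median of 1.25, with 8 rising adjusted over the list alone (camera adjusted p = 3.51e-17, and adjusted p = 0.538 with an estimated correlation). Of 26 NFkB and TNF genes 20 stood higher, at a median of 0.94, with 6 rising adjusted over the list alone (camera adjusted p = 1.38e-09, and adjusted p = 0.538 with an estimated correlation). Cxcl2 was at 455.4 ± 7.95 CPM (SD, n = 2) against 4.96. Primary granule genes stood lower in 5 of 5, at a median of -0.94 (camera adjusted p = 0.00167, and adjusted p = 0.538 with an estimated correlation), with 0 passing over all genes, with Mpo at -1.36 ± 0.43. EdgeR called 0 of 11543 genes, with 659 at an unadjusted p under 0.05 and 113 by DESeq2. With the block it called 380, 338 higher and 42 lower. Among those that rose were Cxcl2 at 6.56 ± 0.56 (adjusted p = 3e-28), Egr1 at 5.63 ± 0.47, Fos at 5.29 ± 0.53 and Ptgs2 at 5.17 ± 0.43. The mitochondrial genes mt-Nd2 and mt-Nd3 fell by 1.63 ± 0.32 and 1.42, against the control with its 920 barcodes above the mitochondrial limit. Without the block the count was 61 without hotspot replicate 1, 199 without hotspot replicate 2, 17 without coldspot replicate 1 and 8 without coldspot replicate 2. Hbb-bs was at 4259 and 14070 CPM in the coldspots against 34.1, and the cluster that held 99.5% of control neutrophils held 8.54% and 2.10% of those of the coldspots.

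In coldspot monocytes, antigen presentation genes stood below the control. The clusters differed here too. The cluster with H2-Ab1 among its leading genes held 62.1% of control monocytes against 6.54% and 0.719% of those of the coldspots, and the cluster led by Fn1 and Ccr2 held 4.56% against 64.1% and 74.1%. This split was not kept with no centring, where a cluster led by Fn1 and Ccr2 held 483 control cells and 117 and 304 of the coldspots. Of 11 MHC class II genes 10 stood lower, at a median of -0.90, with 5 falling adjusted over the list alone and, with the block, 4 over all genes (camera adjusted p = 2.1e-09, and adjusted p = 0.220 with an estimated correlation). With the block Ciita, the transcriptional activator gene of MHC class II, fell by 1.60 ± 0.31 (adjusted p = 4e-05), H2-Ab1 by 1.29 (adjusted p = 0.0016) and H2-Aa by 1.43 (adjusted p = 0.00019); with stricter cells Ciita stood at 0.03. Interferon gamma genes stood lower in 19 of 22, at a median of -0.82, with 4 falling adjusted over the list alone (camera adjusted p = 1.77e-11, and adjusted p = 0.220 with an estimated correlation). Alternatively activated macrophage genes stood lower in 11 of 13, at a median of -1.43 (adjusted p = 2.1e-09, and adjusted p = 0.220 with an estimated correlation). Of 15 complement and efferocytosis genes 10 stood lower, at a median of -0.49 (adjusted p = 0.000629, and adjusted p = 0.220 with an estimated correlation). EdgeR called 0 of 12293 genes, with 424 at an unadjusted p under 0.05 and 11 by DESeq2, and 87 without hotspot replicate 1, 28 without hotspot replicate 2 and 1 without coldspot replicate 2. With the block 291 passed, 150 higher and 141 lower. Fos rose by 5.22 ± 0.39 (adjusted p = 1.5e-34) and Dusp1 by 4.21 ± 0.41. Those that fell included Fcgr4 at -2.09 ± 0.30 (adjusted p = 1.4e-09) and the scavenger receptor gene Cd36 at -1.79 ± 0.30.

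In coldspot macrophages 13 genes passed against the 1 control library of 46 macrophages, 12 higher and 1 lower, under the same assumption on its spread and with the same gap in depth. Several of the named genes were of red cells, with 0 and 54 UMIs of Slc4a1 in the coldspots against 0 in the control, and 4 of 8 red cell transcripts rose. B lineage transcripts stood higher in 9 of 10, at a median of 3.21. Of 14 secondary granule genes 13 stood lower, with 6 falling and 1 rising adjusted over the list alone. With the block 4 genes passed and DESeq2 called 0, with 288 of 6476 at an unadjusted p under 0.05 in edgeR. The count was 3 without hotspot replicate 1, 29 without hotspot replicate 2 and 36 without coldspot replicate 1. Without coldspot replicate 2 the red cell genes Alas2 and Bpgm each stood at -3.39 in place of rising.

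The site difference was then fitted over both weeks with 3 hotspot and 3 coldspot libraries. In mature neutrophils all 25 NFkB and TNF genes stood higher in hotspots, at a median of 0.58 (camera adjusted p = 5.55e-12, and adjusted p = 0.502 with an estimated correlation). Primary granule genes stood higher in 5 of 5, at a median of 0.89, with 4 rising adjusted over the list alone and 0 over all genes (camera adjusted p = 3.92e-14, and adjusted p = 0.402 with an estimated correlation). Ctsg stood at 1.05 ± 0.31 and Mpo at 0.89 ± 0.35. All 8 red cell and all 10 B lineage transcripts stood higher in the same neutrophils, at medians of 0.65 and 0.72, and 8 of 8 red cell transcripts in monocytes, at 0.83. In monocytes complement genes stood higher in 11 of 13, at a median of 0.17 (adjusted p = 6.8e-05, and adjusted p = 0.570 with an estimated correlation). MHC class II genes stood higher in 9 of 11, at a median of 0.27 (adjusted p = 0.0137, and adjusted p = 0.647 with an estimated correlation). Single genes did not pass, with 0 of 10680 in mature neutrophils (56 at an unadjusted p under 0.05), 0 of 11833 in monocytes (47) and 0 of 5302 in macrophages (106) by edgeR and 0 in each class by DESeq2. With the block 5 macrophage genes passed, among them Slpi at -3.53 ± 0.61 (adjusted p = 8.9e-05) and Il1b at 3.83 ± 0.81 (adjusted p = 0.0045). Monocytes gave 1 gene without week 1 coldspot replicate 2, and macrophages 2 without week 1 hotspot replicate 2 and 1 without week 1 coldspot replicate 2.

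Week 22 was compared with week 1 over both sites. In mature neutrophils and monocytes together 954 genes changed, 276 higher and 678 lower at week 22 (622 in mature neutrophils and 332 in monocytes). In mature neutrophils the early response genes Fos, Fosb, Dusp1 and Nr4a1 fell by 1.62 ± 0.37, 2.70 ± 0.50, 2.47 ± 0.37 and 3.44 ± 0.78. Of the list, 5 of 20 immediate early genes fell over all genes and 10 adjusted over the list alone, where 1 rose. Of 25 NFkB and TNF genes 5 fell over all genes and 7 adjusted over the list alone, with Cxcl2 at -4.47 ± 0.61 (adjusted p = 0.015) and Ccrl2 at -4.10 ± 0.55. Proliferation genes fell, 5 of 20 over all genes and 13 adjusted over the list alone, at a median of -1.48, with Mki67 at -1.72 ± 0.39. So did 3 of 5 primary granule genes (5 adjusted over the list alone), with Mpo at -2.01 ± 0.39. Camera called these 4 lists lower (adjusted p = 0.00022, 5.39e-05, 2.57e-07 and 8.14e-05), with adjusted p = 0.534 with an estimated correlation for each. RNA of other cells was lower in the same neutrophils, with 0 of 8 red cell transcripts higher at a median of -2.27 (camera adjusted p = 5.39e-05, and adjusted p = 0.534 with an estimated correlation) and 3 of 10 B lineage transcripts at -1.05.

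Interferon genes were higher at week 22 in mature neutrophils. Of 25 interferon-stimulated genes 4 rose over all genes and 7 adjusted over the list alone, at a median of 0.51 (camera adjusted p = 0.00116, and adjusted p = 0.534 with an estimated correlation). Among them were the viral RNA sensor gene Ifih1 at 0.94 ± 0.22 and Parp14 at 1.12 ± 0.21. Of 14 interferon gamma genes 3 rose over all genes, and adjusted over the list alone 7 rose and 1 fell, with the immunity GTPase genes Irgm2 at 1.42 ± 0.22 and Irgm1 at 1.30 ± 0.29. Jarid2, a cofactor gene of the Polycomb complex, rose by 2.72 ± 0.19 (adjusted p = 0.0011), the lysosomal lipase gene Lipa by 1.26 ± 0.28 and the neutrophil chemokine receptor gene Cxcr2 by 0.85 ± 0.19 (adjusted p = 0.043). The cytokine receptor gene Il31ra fell by 6.17 ± 0.51 (adjusted p = 0.002).

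In monocytes 11 of 24 oxidative phosphorylation genes fell at week 22 over all genes and 16 adjusted over the list alone, at a median of -0.70 (camera adjusted p = 8.81e-10, and adjusted p = 0.638 with an estimated correlation). Atp5e stood at -1.20 ± 0.12 and Cox6c at -1.15 ± 0.12. Of 24 ribosomal protein genes 7 fell over all genes, and adjusted over the list alone 17 fell and 2 rose, with Rps29 at -1.86 ± 0.14. Of 23 proliferation genes 0 passed over all genes and 14 fell adjusted over the list alone, at a median of -1.23. The decoy interleukin 1 receptor gene Il1r2 fell by 4.48 ± 0.61, Dusp1 by 4.01 ± 0.51 and Fos by 2.32 ± 0.36. Lower too in these monocytes stood red cell transcripts, with 1 of 8 higher at a median of -0.97, B lineage transcripts, with 2 of 10 at -0.93, and T and NK lineage genes, with 0 of 4 at -2.63. The lipid receptor gene S1pr5 rose by 1.57 ± 0.22. In macrophages, added after the data were seen, 56 genes changed, 46 higher and 10 lower, with the interferon-induced gene Isg15 at 2.71 ± 0.48 (adjusted p = 0.012) and the fibronectin gene Fn1 at -6.02 ± 1.01 (adjusted p = 0.0087). There 8 of 8 red cell transcripts stood higher, at a median of 2.32, and 13 of 14 secondary granule genes, at 1.24. Week 22 was its own batch, so the week and the batch cannot be told apart. The week 1 and week 22 libraries shared 1 barcode sequence, where the week 1 rate gives 239.1. The week 22 pair shared 28 (18.79 expected), which points to another barcode set. The labels give 1 protocol, and a change of kit was not settled. Neither can be told apart from the week. DESeq2 called 2530 genes, and edgeR 206 without week 1 hotspot replicate 1, 478 without week 1 hotspot replicate 2, 576 without week 1 coldspot replicate 2, 8 without the week 22 hotspot and 13 without the week 22 coldspot.

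Whether the site difference itself changed between the weeks was tested as an interaction, which assumes that the lone week 22 libraries vary like those of week 1. In mature neutrophils 25 of 26 NFkB and TNF genes had a smaller hotspot excess at week 22, at a median of -1.16 (camera adjusted p = 1.5e-12, and adjusted p = 0.503 with an estimated correlation). Il1b stood at -1.69 ± 0.78 and Cxcl2 at -1.70 ± 0.79. In monocytes 10 of 11 MHC class II genes did, at a median of -0.82 (camera adjusted p = 1.08e-09, and adjusted p = 0.323 with an estimated correlation), with Cd74 at -1.20 ± 0.33. So did 11 of 15 complement genes, at a median of -0.78 (adjusted p = 4.57e-07, and adjusted p = 0.323 with an estimated correlation). The complement list also passed by fry (adjusted p = 0.0277), but not with the block (adjusted p = 0.678). B lineage transcripts were higher in 1 of 10 in the mature neutrophil interaction, at a median of -0.71. EdgeR called 0 of 24183 genes over both classes, with 98 at an unadjusted p under 0.05 and 0 by DESeq2. The count was 2 without week 1 hotspot replicate 1 and 9 without week 1 hotspot replicate 2. With the block 23 passed. They included Ccl4 at -2.54 ± 0.46 (adjusted p = 0.00041) in mature neutrophils and, in monocytes, Egr1 at 6.82 ± 0.90 (adjusted p = 1e-10) and Ier3 at -2.37 ± 0.53 (adjusted p = 0.012), which stood at 0.17 without week 1 hotspot replicate 1.

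At week 22 alone the hotspot and the coldspot were 1 library each, so they were not tested against each other and the exact Poisson intervals cover counting error only. In mature neutrophils inflammatory genes stood lower in the hotspot, with 427.9 CPM of Il1b (9149 UMIs) against 685.1 (9621 UMIs), a log2 ratio of -0.68 (interval -0.72 to -0.64), and Cxcl2 at -0.63 (-0.81 to -0.46). The summed NFkB and TNF list held 2086 CPM in the hotspot and 2563 in the coldspot, a log2 ratio of -0.30 (-0.32 to -0.28). The cluster led by Il1b and Csf3r held 42.6% of hotspot and 50.6% of coldspot neutrophils, and the cluster led by Retnlg and Mmp8 56.1% and 47.6%. The list's median of -0.20 lay at percentile 0 of 10000 random lists matched on mean expression. The same held for interferon-stimulated genes, at a median of -0.30, and interferon gamma genes, at -0.33. Wfdc17, an antiprotease-like gene, stood at -1.40 (-1.49 to -1.31), Fcnb (ficolin B) at 2.23 (1.08 to 3.62) and the heme synthesis gene Alas2 at 1.41 (1.07 to 1.76). Red cell RNA had a median of 1.12 (percentile 100).

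Week 22 monocytes held less antigen presentation RNA in the hotspot, with Cd74 at -0.63 (-0.67 to -0.60) and H2-Ab1 at -0.48 (-0.54 to -0.41), and a median of -0.27 over MHC class II (percentile 0). The interferon-induced chemokine gene Cxcl9 had 10 UMIs in the hotspot and 233 in the coldspot, a log2 ratio of -4.67 (-5.75 to -3.77), and Egr1 had 83 against 1, a ratio of 6.24 (3.73 to 11.57). The granule genes Ltf, Camp and Ngp stood higher, at 4.52, 3.93 and 3.56. Transcripts of other cell types stood higher in the same monocytes, with the neutrophil genes S100a9 and S100a8 at 3.15 and 2.53, the red cell genes Rhag and Slc4a1 at 4.73 and 4.16 and the B cell gene Ms4a1 at 3.62. Red cell RNA was higher in 8 of 8 members, at a median of 0.83. In macrophages H2-Ab1 stood at -2.14 (-2.42 to -1.87) and Cd74 at -1.57 (-1.72 to -1.43), MHC class II had a median of -1.57 (percentile 0.00500), and Cxcl9 and the chemokine gene Ccl8 stood at -2.95 and -2.92. Chemotaxis genes had a median of 1.28 (percentile 99.95) in macrophages. Neutrophil RNA stood higher in the same macrophages, with 10 of 11 secondary and tertiary granule genes higher at a median of 1.32 (percentile 100), Lcn2 at 1.32, Cxcr2 at 1.85 and S100a8 at 0.41. The NFkB and TNF sum had a log2 ratio of 0.15 (-0.06 to 0.36), which turned to -0.0796 with TMM factors.

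Donor cells were sought by the feature EGFP, chosen after it had been seen. It stands for the GFP label of the transplanted cells. At week 1 an EGFP UMI was found in 14.6% of the cells of hotspot replicate 1 and 1.41% of hotspot replicate 2, against 0.205% and 0.393% of the coldspot replicates and 0 of 6678 cells of the control, which allows a share of up to 0.0449%. The hotspot mean was 7.98% ± 9.30 against 0.299% ± 0.133 (SD, n = 2; exact two-sided permutation p = 0.333, the smallest possible), a difference of 7.68 points. It was 1.11 points without hotspot replicate 1 and 14.25 without hotspot replicate 2. In hotspot replicate 1 an EGFP UMI was found in 33.7% of erythroid cells, 27.0% of immature neutrophils, 9.89% of mature neutrophils, 8.40% of monocytes and 1.13% of B progenitors, with median depths of 14856, 15073, 5790, 11787 and 5494 UMIs. Thinned to 1000 UMIs per cell these shares were 21.1%, 8.31%, 3.89%, 3.65% and 0.243%. The share that free EGFP RNA gives was not measured, since the control held no EGFP. In this library 11 of 14 B progenitors and 7 of 8 B cells with EGFP held 1 EGFP UMI, so their shares are not read as donor cells. In hotspot replicate 2 the shares were 6.76% of monocytes, 2.04% of erythroid cells, 0.348% of mature neutrophils and 0.321% of immature neutrophils. In coldspot replicate 2, 19 of the 26 cells with EGFP were immature neutrophils. At week 22 EGFP was found in 31.3% of hotspot and 23.5% of coldspot cells, but in 8.86% and 9.40% after thinning, which turns the order. Mature neutrophils stood at 33.4% against 27.4% and, thinned, at 8.26% against 11.1%, with median depths of 11338.5 and 8833 UMIs. B progenitors stood at 44.7% (exact binomial interval 42.2 to 47.1) against 12.8% (10.5 to 15.4). Immature neutrophils stood at 36.2% (33.4 to 39.0) against 3.36% (2.16 to 4.95), with median depths of 25335 and 25147 UMIs, and NK cells at 21.9% (13.1 to 33.1) against 52.9% (42.8 to 62.9). Thinned, these shares were 12.3% against 4.22%, 5.24% against 0.565% and 9.59% against 18.6%. Thinning left out 107 cells of hotspot replicate 1, 179 of the week 22 hotspot and 114 of the week 22 coldspot as too shallow. The sort by GFP before capture can set the shares of whole libraries.

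**Figure D3:**
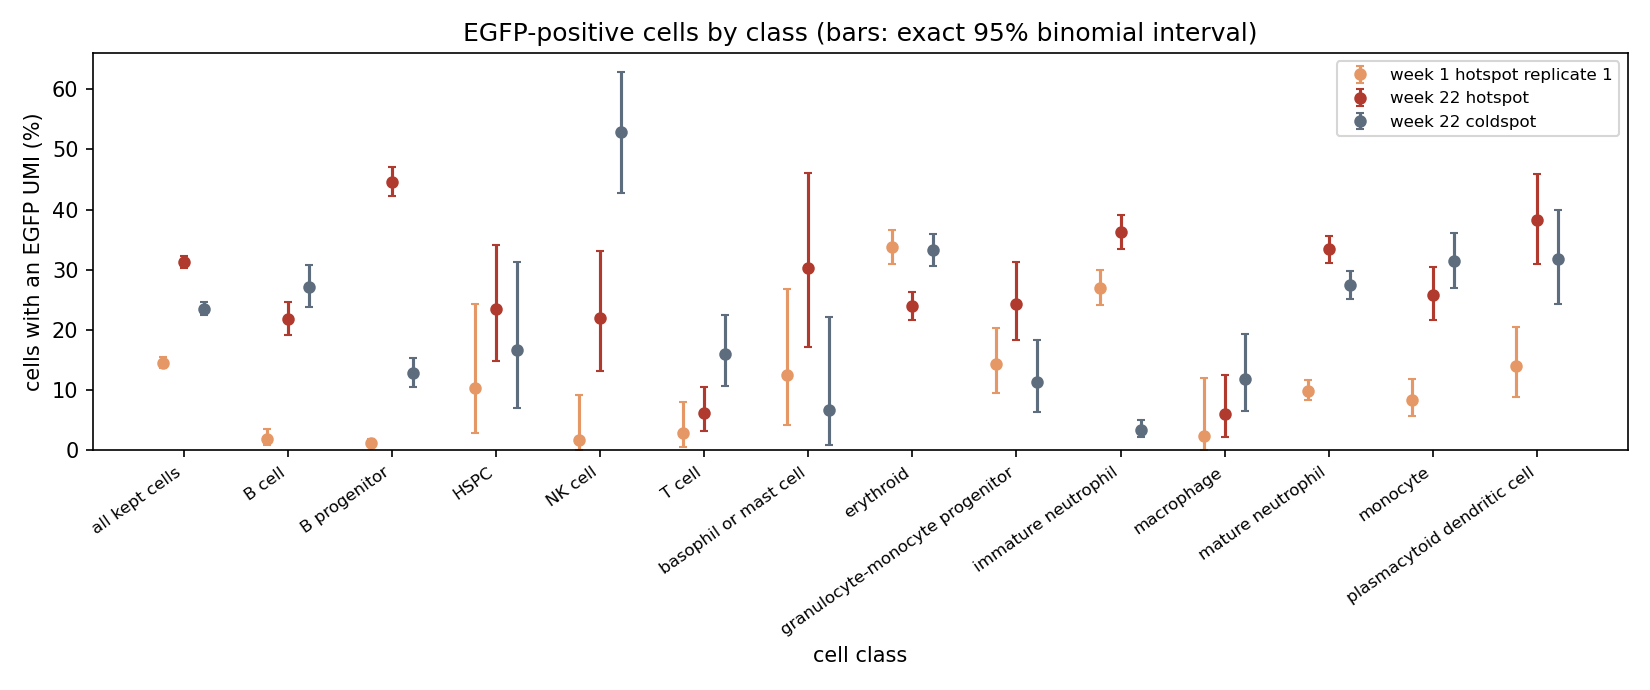
Percent of cells with at least 1 EGFP UMI (vertical axis) in each cell class of 3 libraries, with exact 95% binomial intervals as bars that cover counting error only. At week 22 immature neutrophils stood at 36.2% in the hotspot and 3.36% in the coldspot, and NK cells at 21.9% and 52.9%.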

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

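The tests on stem and progenitor cells alone and on handling of the hotspot replicate 1 suspension were chosen after the result was seen. So was every use of EGFP.

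In mature neutrophils the NFkB and TNF list had a median log2 hotspot to coldspot ratio of 1.28 in batch 1 and 0.31 in batch 2 but -0.20 at week 22, from 1 library per site, a difference in sign that was not tested. A cluster led by Cxcl2 and Il1b, with 320 of its 407 cells from hotspot replicate 1, is not the whole cause at week 1, since the list kept a median of 0.881 in batch 1 without it. Handling of the hotspot replicate 1 suspension may account for part of the height, because in batch 1 the list's median lay above 0.2 in 100.0% of the other classes (11 of 11), and in 6 of 10 of batch 2, which that handling did not touch. An inflamed site, which would also reach many cell types, predicts the same and stays open and untested. A cluster led by Il1b and Csf3r followed the list's sign, with 50.1% of hotspot and 38.8% of coldspot neutrophils in batch 2. At week 22 it held 42.6% and 50.6%, and what it adds was not tested.

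Immediate early genes were lower in the control than in both sites at week 1, with Fos in mature neutrophils at 22.4 CPM against 381 to 1065. Handling that acts on every cell type cannot be told apart from a site effect, since the list's median lay above 0.5 log2 in 70.0% of the other classes (7 of 10), between the bounds of 80% and 50% set for it. Neutrophil RNA free in the droplets may carry part of it into other classes, because Fos UMIs per S100a8 UMI in 4 other classes stood at 1.23 times those of mature neutrophils, as a median. It is not the source in stem and progenitor cells, where that ratio was 8.93 at the lowest of the 4 hotspot and coldspot libraries. The absence of mutant cells stays open and untested.

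Other lists also had opposite signs at the 2 weeks, and these differences were not tested between the pairs. In mature neutrophils classically activated macrophage genes stood at -0.187 at week 22 against 1.09 in batch 1 and 0.313 in batch 2, iron and heme recycling at -0.19 against 0.210 and 0.115, and ribosomal proteins at -0.190 against 0.410 and 0.0541. Immediate early genes stood at -0.14 against 0.76 and 0.25. In monocytes the NFkB and TNF list stood at -0.0272 against 0.656 and 0.129, MHC class II at -0.269 against 0.669 and 0.567, and immediate early genes at -0.0607 against 0.227 and 0.0571.

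EGFP, a feature outside the comparisons of endogenous genes, stood above the control's 0 of 6678 cells (a share of up to 0.0449%) in each hotspot and coldspot library. It was found in 14.6% and 1.41% of cells in the week 1 hotspots, 0.205% and 0.393% in the week 1 coldspots, 31.3% in the week 22 hotspot and 23.5% in the week 22 coldspot. Thinned to 1000 UMIs per cell, the week 22 shares were 8.86% and 9.40%, in the opposite order.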

How the results depend on the processing

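Choices added after the data were seen were the macrophage minimum of 5 cells, macrophages in the comparisons of weeks, the fit without the Cxcl2 and Il1b cluster, the matchings, leaving out libraries for the shares, and all EGFP settings. Over 24 results and 229 alternatives, 117 values stayed within their bounds, 111 moved and 1 reversed. Over 245 named genes by comparison and class, 1911 alternatives kept the side of the threshold, 385 passed it newly, 365 lost it and 28 reversed. The cause was not tested for any of these. Depth limits coldspot replicate 1, with 23796276 UMIs and 9 macrophages. Where a left-out library leaves an arm with 1 sample, that sample is assumed to vary like the other groups. Stricter cells left too few macrophages and were not run there. No paired analysis was possible because week 22 is its own batch for week 22 against week 1, and because there is 1 pair at week 22 alone.

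Counts of genes for mature neutrophils, monocytes and macrophages in turn moved as follows. Hotspot against coldspot at week 1 (0, 0 and 0) gave 1, 1 and 7 with no filter on low counts and 14, 8 and 1 with the replicate block, and macrophages 5 with no centring. Without the Cxcl2 and Il1b cluster neutrophils gave 0, and 11 with the block. Hotspot against control (4, 0 and 68) gave 202, 27 and 2 by DESeq2, 279, 148 and 22 with no filter, 567 and 322 with the block, 12, 2 and 45 with no centring, 11 in neutrophils and 44 in macrophages with doublets kept, and 0 in neutrophils with stricter cells. Coldspot against control (0, 0 and 13) gave 113, 11 and 0 by DESeq2, 183, 107 and 3 with no filter, 380, 291 and 4 with the block, and in neutrophils and macrophages 8 and 7 with doublets kept and 4 and 2 with no centring. Hotspot against coldspot over both weeks (0, 0 and 0) gave 2, 41 and 4 with no filter, and in macrophages 5 with the block, 1 with doublets kept and 2 with no centring. The other classes (1) gave 7 by DESeq2, 265 with no filter, 85 with the block, and 0 with doublets kept, with stricter cells and with no centring. Week 22 against week 1 (954) gave 2530 by DESeq2 and 4073 with no filter. The interaction (0) gave 1 with no filter, 23 with the block and 2 with macrophages included. EGFP-positive B progenitors (114) gave 213 with RLE size factors, 34 by DESeq2, 299 with no filter, 0 without the library block, and 3, 11 and 9 when matched on depth, cluster and both. The 6 other classes (6) gave 24, 135 and 0 by DESeq2, with no filter and without the library block. The replicate block changed no other count by over 1.5 times, and among the lists named it changed only the calls given with it. The week 22 NFkB and TNF sum ratio moved from -0.297 to -0.269 in neutrophils with no centring and from 0.150 to -0.0796 in macrophages with TMM factors.

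With 1 library left out, hotspot against coldspot at week 1 ranged from 0 to 0, 0 to 3 and 7 to 21, hotspot against control from 20 to 386, 0 to 91 and 41 to 165, coldspot against control from 8 to 199, 0 to 87 and 3 to 36, and both weeks from 0 to 0, 0 to 1 and 0 to 2. The other classes ranged from 132 to 596, week 22 against week 1 from 8 to 974, the interaction from 0 to 9, and EGFP from 29 to 203 in B progenitors and 2 to 49 elsewhere. Share differences ranged from -7.38 to -1.54 points in mature neutrophils, -1.85 to -0.295 in monocytes and -0.0323 to 0.306 in macrophages, where the sign turned without coldspot replicate 1, and from 1.11 to 14.25 for EGFP.

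Single genes reversed in fits without a block unless one is named, and the ranges are those with 1 library left out. For hotspot against coldspot at week 1, Hspa1a of HSPCs ranged from -11.12 to 3.51 and Hspa1b of monocytes from -6.0 to 4.24, the latter value in each without coldspot replicate 1. In mature neutrophils Tnfaip3 ranged from -0.35 to 3.05 and Fosl1 from -0.0068 to 2.85. Ier3 of monocytes ranged from -0.51 to 4.34 and Ifitm1 of plasmacytoid dendritic cells from -0.62 to 4.26. These 4 were lowest without hotspot replicate 1. H2bc14 of the latter class ranged from -2.55 to 0.10, highest without coldspot replicate 2. S100a8 (-1.47) and S100a9 (-1.78) of NK cells reversed with doublets kept, and Cd69 of plasmacytoid dendritic cells (0.76) with no centring.

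For hotspot against control, Fpr3 of mature neutrophils ranged from -1.61 to 0.12 and H1f4 of monocytes from -0.11 to 1.97, reversed without hotspot replicate 2. Gcnt2 of monocytes ranged from -1.92 to 2.20, reversed without hotspot replicate 1, and stood at -1.58 with the replicate block. For coldspot against control, H1f4 of monocytes ranged from -1.08 to 2.23 and, in macrophages, Alas2 from -3.39 to 7.98 and Bpgm from -3.39 to 7.89, each lowest without coldspot replicate 2. Ciita of monocytes stood at 0.0331 with stricter cells. Between weeks, Fam220a of macrophages reversed (-3.16) with no filter. In the monocyte interaction, Hspa1a ranged from -3.38 to 11.25 and Hspa1b from -1.22 to 9.01, lowest without coldspot replicate 1, and Cd63 from -0.18 to 3.33 and H3c3 from -2.90 to 4.17, lowest without coldspot replicate 2. Ier3 ranged from -4.69 to 0.17, highest without hotspot replicate 1. With doublets kept Ebf1 stood at -0.21 and H3c3 at -0.0828, and with no centring H3c3 stood at -0.16 and Cenpf at -0.22.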

Other observations

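The tests of cluster mix, of the splits for hotspot against coldspot over both weeks and of the splits for EGFP-positive granulocyte-monocyte progenitors, mature neutrophils and plasmacytoid dendritic cells were chosen after the result was seen, as was the EGFP comparison itself.

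Cells with an EGFP UMI were compared with the cells without one in the same libraries, with the library as a block. Free EGFP RNA was not measured and can put host cells among the EGFP-positive, and 11 of 14 such B progenitors of week 1 hotspot replicate 1 held 1 EGFP UMI. In B progenitors 114 genes differed, 52 higher and 62 lower in EGFP-positive cells (1136 of 13291 at an unadjusted p under 0.05). Of 23 proliferation genes 5 rose over all genes and 13 adjusted over the list alone, with Ube2c, which marks cyclins for breakdown, at 0.72 ± 0.14 (SE; adjusted p = 0.000888) and the kinase gene Cdk1 at 0.60 ± 0.14 (adjusted p = 0.00921). Ms4a1, the gene of CD20, fell by 1.07 ± 0.16 (adjusted p = 3.33e-06). Of 10 B lineage transcripts all stood lower, at a median of -0.36, with 1 falling over all genes and 4 adjusted over the list alone (camera adjusted p = 0.000102, and adjusted p = 0.512 with an estimated correlation). Tet2 stood at -0.22 ± 0.17 (adjusted p = 0.869). The count was 203 without week 1 hotspot replicate 1 and 29 without week 1 hotspot replicate 2, 34 by DESeq2 and 0 without the library block. The balance of higher and lower genes turned with RLE size factors (125 and 88), by DESeq2 (22 and 12) and without the week 22 hotspot (46 and 33) or coldspot (59 and 22), and was 4 and 25 without week 1 hotspot replicate 2.

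In 6 other classes 6 genes passed, 4 higher and 2 lower (1356 of 64065 at an unadjusted p under 0.05), and DESeq2 called 24. Monocytes gave 4, among them the panel gene Cxcl2 at 3.23 ± 0.29 (adjusted p = 0.00171; higher in 3 of 4 libraries), Hspa1a at -4.05 ± 0.51 and Tent5c, a leading gene of erythroid clusters here, at 2.67 ± 0.23. Red cell transcripts stood higher in 8 of 8 in EGFP-positive monocytes, at a median of 2.10. In mature neutrophils edgeR called 0 of 9925 genes, with 115 at an unadjusted p under 0.05 and 0 by DESeq2. There 22 of 24 interferon-stimulated genes stood lower in EGFP-positive cells, at a median of -0.49 (camera adjusted p = 3.65e-14, and adjusted p = 0.668 with an estimated correlation). The summed count was 49 without week 1 hotspot replicate 1, 2 without week 1 hotspot replicate 2, 20 without the week 22 coldspot and 13 without week 1 coldspot replicate 2.

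All 23 proliferation genes stood higher in EGFP-positive B progenitors, at a median of 0.36 (camera adjusted p = 4.1e-16, and adjusted p = 0.444 with an estimated correlation). Deeper cells being called EGFP-positive more often may account for it, since the median was -0.0318 when EGFP-negative cells were matched on UMIs, with median depths in the week 22 hotspot of 11025 UMIs in EGFP-positive and 9329.5 in EGFP-negative cells, and of 10754 and 10443 once matched. Cycling cells hold more RNA, so matching on depth can also take away a real difference. Another mix of clusters is left open by a median of 0.222 with cells matched on cluster, and matching on both was tried first and gave 0.0501, each from 1 random draw. A change by the mutation in donor cells stays open and untested, and under the 3 matchings 3, 11 and 9 genes passed, of which 3, 7 and 6 were among the 114.

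Other splits of the same sums into groups of the same sizes were counted. For B progenitors 3 of 32 splits gave at least 114 genes, so chance was not excluded. The highest of the others gave 185, with the EGFP-positive sums of both week 1 hotspots and both sums of the week 22 hotspot on 1 side, which points to a structure of the samples. Among the 8 splits that part every library's pair, 1 gave as many, the real one, and the highest other gave 27; the remaining splits put both sums of a library on 1 side. Chance was not excluded for erythroid cells (22 of 32 splits, real count 1, highest other 60), immature neutrophils (6 of 32, 1 and 94) and monocytes (9 of 32, 4 and 18), where among the 8 pair-parting splits 6, 2 and 3 gave as many and the highest others gave 5, 14 and 5. The high counts of other splits again point to a structure of the samples, and 3 of 35 splits could not be fitted where 32 are given. The splits could not decide for granulocyte-monocyte progenitors, mature neutrophils and plasmacytoid dendritic cells (10 of 10 each, real count 0, highest other 81, 1 and 211). Every split reaches a real count of 0, and 10 splits are also too few for a share under 0.05. The same held for hotspot against coldspot over both weeks in mature neutrophils, monocytes and macrophages (10 of 10 each, real count 0). There the highest other splits gave 19, 5 and 55 genes, with week 1 hotspot replicate 1 and both week 22 libraries on 1 side, a split that mostly follows the week, and the 4 splits that part all 3 pairs gave 0.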
